A study of Mus musculus with 18 samples.

How the data were processed

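RNA was taken from monocytes sorted from spleens of 18 mice on day 3, in 6 groups of 3 independent mice per the series' design text, and libraries were made with a stranded messenger RNA kit per the labels' protocols. The titles also carry codes whose meaning is not given, and some codes are shared by 2 libraries, Dectin-1 knockout PBS replicates 2 and 3 among them, so the independence of the mice rests on the design text. Reads were aligned to GRCm39 with STAR, per the submitters' processing notes, whose edgeR step is not used here. Counts per gene were made with featureCounts 2.0.2 on Ensembl release 104 genes, per the file headers, and deposited by the authors as raw counts with the exon length of each gene in bases. The recorded command allows a read to count for each gene it overlaps and sets no strand option, so overlapping and antisense genes are not separated, and counts of near-identical families are uncertain. Of the deposited columns 18 matched no sample and were not used. All 55416 genes have an identifier, and 1492 have no symbol, hold 0.125% to 0.450% of the counts of a library and were kept in the library totals. Groups were taken from the genotype and treatment labels. Replicate numbers follow accession order and only name the libraries.

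From the deposited counts, genes passing filterByExpr over the 6 groups were kept (17040 genes), scaled by TMM, and tested with the quasi-likelihood F-test of edgeR 4.0.16 (R 4.3.3) in 1 model over the 18 libraries, with 12 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison, and 8 comparisons were made. CPM values use TMM-scaled library sizes, and log2 CPM a prior count of 2. Fold changes on the log2 scale are given with standard errors. The 29 gene lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation. Of all list tests 68 passed with the preset correlation and 4 of these also with an estimated one, the non-classical markers in 3 comparisons and erythroid markers in 1. Targeted genes were compared by an exact two-sided permutation test, and calls near them by Fisher's exact test within 10 Mb. These tests were run in R, and figures were drawn in Python 3.11.15 with numpy 2.4.6.

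These choices, the lists and the rule for named genes were fixed before the data were examined, except for the legacy setting of the test and the sign of a list. The plan named the quasi-likelihood test without its legacy setting, an early look at the counts used the default of this edgeR version, which is the legacy fit, and the non-legacy fit was then taken as the main test because the legacy fit was already listed as the variation to try. The rule for named genes takes up to 6 higher and 6 lower called genes with an absolute log2 fold change of at least 1, a mean of at least 1 CPM and no overlap between the groups, leaving out gene models without a proper symbol, antigen receptor segments and sex-linked transcripts. It adds up to 4 called members of each list, or 2 with the smallest unadjusted p as values where none passed. It always includes Clec7a, Fcgr2b, Fcgr1, Fcgr3 and Fcgr4, and up to 6 called genes near the targeted gene.

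Settings also run, as fixed beforehand, were DESeq2 1.42.0, RLE size factors, no low-count filter and a stricter one (1 CPM in 3 libraries), the legacy quasi-likelihood fit, removal of immunoglobulin, haemoglobin and mitochondrial genes, a fold threshold, own groups only, windows of 5 and 20 Mb, and each library left out in turn. Added after the data were seen were limma voom with quality weights, removal of the most alike WT pair with and without the shallow library, and removal of each library's trend of expression on gene length by a spline with 4 degrees of freedom. The length correction was first run with genes of at least 2 average log2 CPM setting the trend and no centring. After its result was seen it was revised to genes of at least 5 and a trend centred on its median, because the uncentred trend also rescaled the shallow library and better counted genes were wanted to set it. Centring and the minimum changed together, and the revision lowered the value it was meant to test, so all 4 combinations were run, with the preset and with an estimated correlation, and are named the first, centred, abundant-gene and revised forms. That the first form had left part of the length trend was learned only afterwards. The sign of a list was also taken from its median in place of the direction of camera after the first such comparison was seen, since the median is the value printed.

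WT PBS replicate 3 and WT IVIg replicate 1 were the most alike of 153 pairs (Spearman 0.988), though they differ in treatment. Their counts differed by more than sampling noise (chi-square per degree of freedom 48.3, and 36.7 or more in all pairs), which shows only that they are not copies of 1 library. Both were kept, and a label swap or shared batch cannot be decided. Floors of 3 counts cover counting error only, since reads without molecular identifiers are not independent molecules. The test was checked on simulated counts with 200 changed genes. For WT IVIg against PBS (16452 genes in that step) edgeR recovered 12.4% of genes changed 2-fold and 56.7% of those changed 4-fold, with 15 false calls. For the difference in IVIg effect between Dectin-1 knockout and WT (16432 genes) it recovered 1.01% and 15.5%, with 2 false calls. For FcgRIIb knockout against WT (16435 genes) it recovered 3.06% and 50.5%, with 2 false calls. Changes of 2-fold were therefore mostly undetectable here. In these simulations camera passed 0 lists. Their genes were drawn independently of each other, without a length trend, so this cannot check the preset correlation on real lists.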

Results

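RNA was sequenced from monocytes sorted from mouse spleens on day 3 after intravenous immunoglobulin (IVIg, pooled immunoglobulin G) or phosphate-buffered saline (PBS). The 18 libraries came from 6 groups of 3 independent mice: C57BL/6 wild type (WT), Dectin-1 knockout and FcgRIIb knockout animals, each with PBS or IVIg. Dectin-1, encoded by Clec7a, is a beta-glucan receptor, and FcgRIIb, encoded by Fcgr2b, is the inhibitory Fc gamma receptor. The series asks whether these receptors shape the response of monocytes to IVIg. Total counts lay between 16996494 and 48958909 in 17 libraries, and FcgRIIb knockout PBS replicate 2 held 719494 counts. In that library 3 counts correspond to 4.17 CPM (counts scaled by library size), against 0.0613 to 0.177 CPM in the others, so genes of low abundance were not measurable there. Lyz2, the lysozyme of myeloid cells, took the most counts in each library.

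Clec7a (ENSMUSG00000079293, chromosome 6, 129438554 to 129449742, GRCm39) was nearly absent from the Dectin-1 knockout. It stood at 1.89 ± 1.33 CPM (SD, n = 6) there, with a range of 0.247 to 4.05, and at 671 ± 174 CPM (SD, n = 12) in the other libraries, with a range of 360 to 956. The difference was -8.78 on the log2 scale (exact two-sided permutation test, p = 5.39e-05, the smallest that 18564 assignments can give). Fcgr2b (ENSMUSG00000026656, chromosome 1, 170786186 to 170804116) was lower in the FcgRIIb knockout, with transcript remaining. It stood at 182 ± 50.4 CPM (SD, n = 6) there and 248 ± 38.2 CPM (SD, n = 12) elsewhere, 73.5% of the level of the other libraries (exact two-sided permutation test, p = 0.00420). The ranges overlapped, at 130 to 250 CPM in the FcgRIIb knockout and 208 to 318 CPM elsewhere. The deleted part of Fcgr2b is not given in the sources used here, so a count over the whole gene is a weak check of that label.

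**Figure D1:**
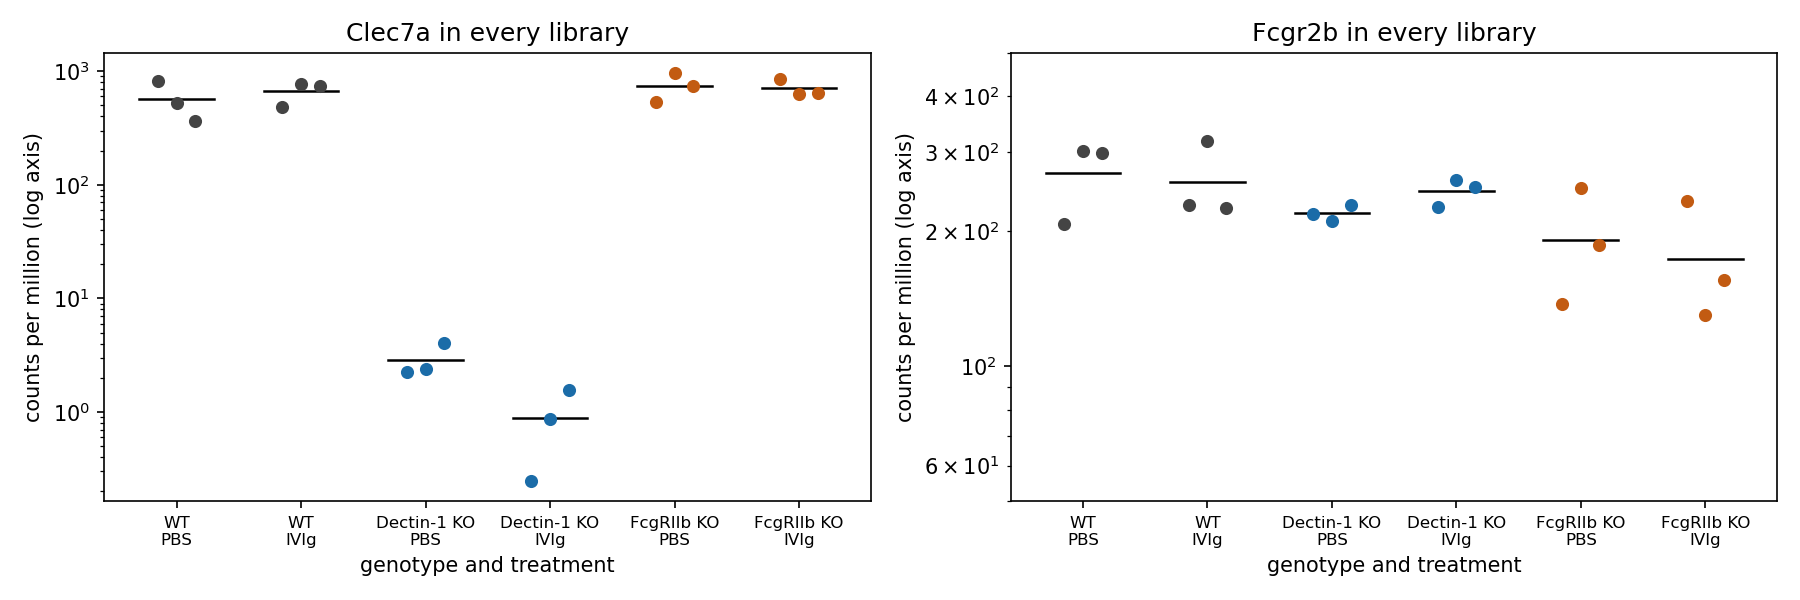
CPM of Clec7a (left) and Fcgr2b (right) on log axes in each of the 18 libraries by genotype and treatment, with a bar at the mean of each group. Clec7a lies between 0.247 and 4.05 CPM in the Dectin-1 knockout and at 360 CPM or more elsewhere, while the Fcgr2b ranges of the genotypes overlap.

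Without IVIg, 5 of the 6 genes other than Clec7a that differed between the Dectin-1 knockout and WT lay within 10 Mb of Clec7a on chromosome 6. Hebp1, a heme-binding protein, was 24.4-fold higher (3.27 ± 1.63 CPM in WT and 81.3 ± 13.5 in the knockout, SD, n = 3 each). Emp1, an epithelial membrane protein, was 23.4-fold higher, and Klra17, of the Ly49 receptor family, was 15.0-fold higher. Eps8, a regulator of actin, was 11.9-fold lower. Klri2, a killer cell lectin-like receptor, had no counts in any of the 3 knockout libraries and 5.41 CPM in WT, at least 176-fold lower against a floor of 3 counts over the group. With Clec7a and the gene model Gm9574 these made up the 7 of 17040 tested genes called by edgeR, 3 higher and 4 lower. Adjusted p in edgeR was 5.10e-07 for Hebp1, 0.000111 for Emp1, 3.11e-06 for Klra17, 3.11e-06 for Eps8 and 0.0199 for Klri2. Within 10 Mb of Clec7a, 5 of 224 genes were called, against 1 of 16815 elsewhere (two-sided Fisher's exact test, p = 2.23e-09). Within 5 Mb 2 of 130 genes were called, against 4 of 16909 elsewhere (p = 0.000849), and within 20 Mb 5 of 367, against 1 of 16672 (p = 2.66e-08, two-sided Fisher's exact tests). The 5 genes differed in the same direction between the IVIg libraries of both genotypes, with an edgeR adjusted p of 0.00359 or less. Reads of Klra17 and Klri2 may be shared with close paralogs, so their levels are uncertain.

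The calls of Klri2 and Gm9574 were lost without some libraries, unlike those of Hebp1, Emp1, Klra17, Eps8 and Clec7a. Klri2 had 0 counts in all Dectin-1 knockout and 128 or more in all WT libraries. Klri2 missed the edgeR threshold without WT PBS replicate 2 (adjusted p = 0.0835), Dectin-1 knockout PBS replicate 1 (0.122), 2 (0.166) or 3 (0.0929), or FcgRIIb knockout PBS replicate 2 (0.157), with own groups only (0.147) and with the first form of the length correction (0.0545). Gm9574 (chromosome 17), named outside the rule after its values were seen, had 228, 30 and 273 counts in the WT PBS libraries and 9, 9 and 1 in the knockout (edgeR adjusted p = 0.0251). Its edgeR call was lost without WT PBS replicate 1 (adjusted p = 0.215) or 3 (0.119), or Dectin-1 knockout PBS replicate 1 (0.278), 2 (0.404) or 3 (0.525). It was also lost without Dectin-1 knockout IVIg replicate 3 (edgeR adjusted p = 0.0551) or FcgRIIb knockout IVIg replicate 1 (0.0521), 2 (0.0529) or 3 (0.0525). DESeq2 (adjusted p = 0.388) and limma voom (0.331) did not call Gm9574, nor did edgeR with the legacy fit (1), own groups only (0.322) or the most alike WT pair left out (0.0913). DESeq2 and limma voom called 12 genes each, and edgeR 16 without the most alike WT pair.

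**Figure D2:**
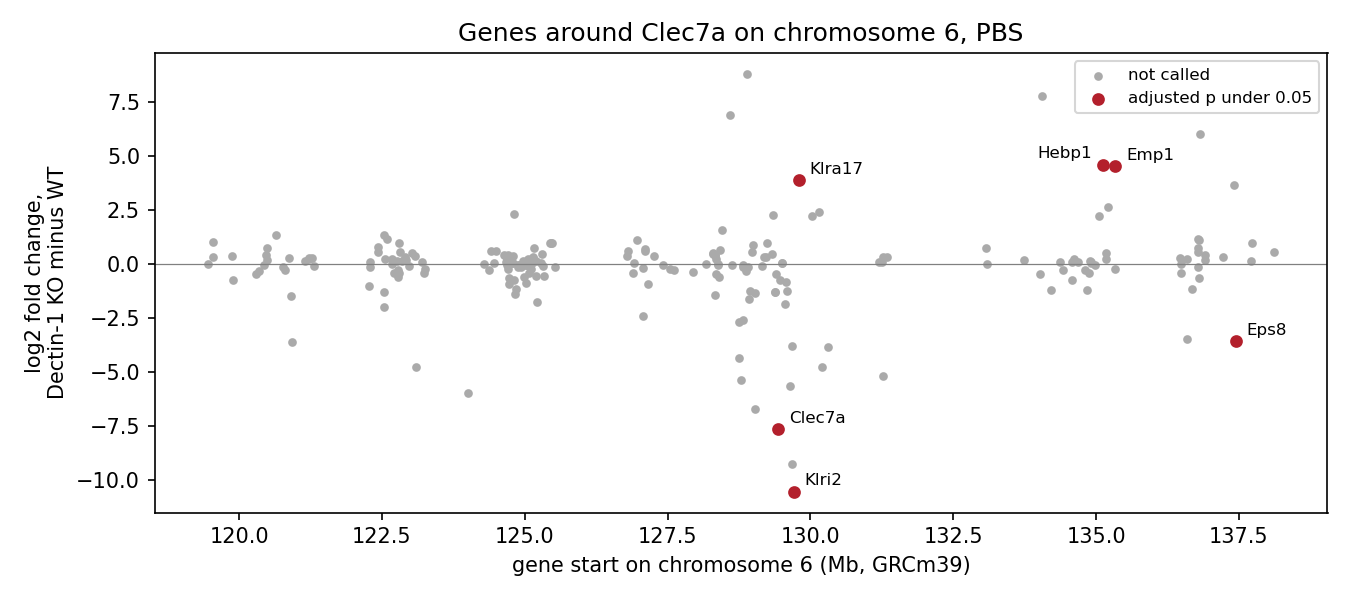
Log2 fold change of Dectin-1 knockout against WT in PBS for Clec7a and the 224 tested genes within 10 Mb of it, by gene start on chromosome 6 in Mb (GRCm39), with genes of adjusted p under 0.05 in red and named. Hebp1, Klra17 and Emp1 lie above 0 and Eps8, Klri2 and Clec7a below, and the plotted value of Klri2, with 0 counts in the knockout, depends on the prior count of the fit.

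Among the lists fixed in advance, 12 of 29 passed camera in this comparison, and 2 of them also passed with an estimated correlation. Non-classical monocyte markers, genes of patrolling monocytes, were higher, with 24 of 28 members up and a median log2 fold change of 0.42 (camera adjusted p = 2.69e-13, and adjusted p = 0.0358 with an estimated correlation). Of these, 8 passed adjusted over the list alone and 0 over all genes in edgeR. Cd300e, an activating receptor, stood at 122 ± 40.4 CPM in WT and 257 ± 58.7 in the knockout (SD, n = 3 each), and Eno3, a muscle-type enolase, gave a log2 fold change of 1.30 ± 0.35 (SE). Erythroid markers were higher by a median of 1.01 (camera adjusted p = 5.30e-05, and adjusted p = 0.0358 with an estimated correlation), with Hbb-bt, a beta globin, at 2.37 ± 0.73. Without immunoglobulin, haemoglobin and mitochondrial genes the erythroid call was lost, at a median of 0.62 (camera adjusted p = 0.0749), and with no low-count filter the median was 0.58. The respiratory chain list had 59 of 59 members up and a median of 0.43 (camera adjusted p = 6.32e-16, and 0.401 with an estimated correlation), with Ndufa5 of complex I at 1.10 ± 0.42. Cell cycle genes had a median of 0.44 with Ccnb2, a mitotic cyclin, at 1.93 ± 0.70 (camera adjusted p = 2.00e-07, and 0.314 with an estimated correlation). T cell markers had a median of -0.98 with 20 of 22 members lower and Thy1 at -1.30 ± 0.57 (camera adjusted p = 2.67e-06, and 0.0742 with an estimated correlation). NK cell markers had a median of -0.40, led by Klri2 (camera adjusted p = 0.000207, and 0.107 with an estimated correlation). Of 20 members 9 lie within 10 Mb of Clec7a. The other 11 had a median of 0.32. No other list was split by distance. Fold changes in this comparison ran with gene length (Spearman rho = -0.52 across 5281 abundant genes, which are not independent replicates). With the trend set by abundant genes, uncentred and centred, medians were 0.27 and 0.26 for non-classical markers and 0.25 and 0.24 for the respiratory chain, and both lists still passed with the preset correlation. With an estimated correlation the non-classical call was then lost (camera adjusted p = 0.246 and 0.0726, and 0.550 in the first form), as was the erythroid call (0.0898 and 0.0611).

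The remaining 6 called lists passed only with the preset correlation. Higher medians were 0.18 for MHC class I presentation (adjusted p = 0.621 with an estimated correlation), 0.16 for the lysosome (0.621) and 0.26 for red pulp macrophage markers (0.401). Lower medians were -0.21 for the unfolded protein response (0.382), -0.22 for immediate early genes (0.335), with Egr1 at -3.04 ± 0.76, and -0.09 for C-type lectins (0.0934), a list that holds Clec7a itself. Camera lost the MHC class I (0.20), C-type lectin (-0.05) and red pulp (0.26) lists without Dectin-1 knockout PBS replicate 2, and cell cycle and NK cell medians were then 0.29 and -1.04. Dropping WT PBS replicate 1 ended the MHC class I (0.14), C-type lectin (-0.11) and red pulp (0.39) calls and gave -0.34 for immediate early genes. Red pulp markers (0.19) lost theirs without Dectin-1 knockout PBS replicate 1, which left the lysosome at 0.10, and MHC class I (0.12) without replicate 3, which left C-type lectins at -0.02 and red pulp at 0.42. The unfolded protein response (-0.18) lost its call without WT PBS replicate 2, which left C-type lectins at -0.06 and immediate early genes at -0.14. The lysosome (0.06) lost its call without WT PBS replicate 3, which left C-type lectins at -0.02 and NK cell markers at -0.09.

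Other settings moved these lists as well. All 4 forms of the length correction ended the MHC class I call (0.04 to 0.12), 3 the red pulp call (0.21 to 0.27) and the first form the lysosome call (0.13), and the abundant-gene forms gave 0.10 and 0.08 for the lysosome and -0.35 and -0.34 for immediate early genes. C-type lectins had -0.14, -0.17 and -0.18 in the centred, abundant-gene and revised forms, and their call was lost with no low-count filter (-0.13) and with own groups only (-0.07). With no low-count filter the MHC class I call was lost too (0.14). Without the most alike WT pair, with the shallow library kept or left out, the lysosome call was lost (0.05 and 0.06), and medians were -0.04 and -0.02 for C-type lectins and -0.11 and -0.09 for NK cell markers. The NK cell median was -0.69 with no filter and -0.65 with the stricter filter and with own groups only.

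The FcgRIIb knockout in PBS had more immunoglobulin and respiratory chain transcript than WT by camera with the preset correlation. With an estimated correlation adjusted p was 0.212 for plasma cell markers and 0.428 for the respiratory chain. Plasma cell markers had a median log2 fold change of 3.06, with 11 of 15 members up. Their call was lost without immunoglobulin, haemoglobin and mitochondrial genes (0.77, camera adjusted p = 0.130), and their median was 0.65 with own groups only. Jchain, the joining chain of polymeric antibodies, stood at 8.37 ± 5.95 CPM in WT and 320 ± 333 in the knockout (SD, n = 3 each), and Mzb1, a plasma cell chaperone, gave 3.06 ± 0.69 (log2 fold change and SE). The respiratory chain list had 58 of 59 members up and a median of 0.86, with Ndufs8 of complex I at 1.06 ± 0.29 and Cox7b of complex IV at 1.24 ± 0.35. Its median was 0.39 without FcgRIIb knockout PBS replicate 3, the library of this comparison with the strongest tilt toward short genes, and 0.49 and 0.37 with the abundant-gene and revised forms of the length correction. Immunoglobulin genes took 0.143% to 0.290% of counts in these FcgRIIb knockout libraries and 0.0316% to 0.0341% in WT. By gene, edgeR called 0 of 17040, with 1643 at an unadjusted p under 0.05 against 852 by chance, 1047 higher and 596 lower. The excess depended on settings and libraries, at 769 (728 by chance) with own groups only, 895 (886) without the most alike WT pair, 1009 with limma voom, 811 (898) without WT PBS replicate 3, and 3811 (908) and 429 (906) without FcgRIIb knockout PBS replicates 1 and 3. DESeq2 called 209 and limma voom 0, and edgeR 10 with no low-count filter and 8 with own groups only. In edgeR 40 were called without FcgRIIb knockout PBS replicate 1, 9 without WT IVIg replicate 3, 8 without WT IVIg replicate 1, and 1 each without WT IVIg replicate 2 and FcgRIIb knockout PBS replicate 3. Within 10 Mb of Fcgr2b edgeR called 0 of 206 genes (1 without FcgRIIb knockout PBS replicate 1), and 0 of 16833 elsewhere. With no calls Fisher's exact test can show nothing.

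With the preset correlation 7 lists passed camera in this comparison, and 0 did with an estimated one. Adjusted p was then 0.428 for the B cell, MHC class II and Fc receptor lists, 0.667 for classical markers and 0.212 for C-type lectins. Adjusted p in camera was 5.38e-24 for the respiratory chain and 0.000191 for plasma cell markers. In edgeR 35 of the 59 respiratory chain genes passed adjusted over the list alone and 0 over all genes. B cell markers had a median of 0.60 (camera adjusted p = 0.000768), led by Igkc, an immunoglobulin light chain, at 4.67 ± 0.83. MHC class II genes had a median of 0.32, with H2-DMb1 at 0.80 ± 0.25, and classical monocyte markers one of 0.40, with Ms4a4c at 1.04 ± 0.35. Genes of Fc gamma receptor signalling had a median of -0.24, with Vav3 at -1.04 ± 0.28 and Cblb at -1.34 ± 0.40. Camera called C-type lectin genes higher while 15 were higher and 13 lower, with a median of 0.03 and Clec4b1 at 1.51 ± 0.32. The length trend was strongest here (Spearman rho = -0.60 across 5281 genes, which are not independent replicates).

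Single libraries decided several of these lists. Leaving out FcgRIIb knockout PBS replicate 1 ended the B cell call and turned its median to -0.12, and gave medians of 0.53 for MHC class II, 0.62 for classical and 0.14 for C-type lectin genes. Leaving out replicate 2 of that group ended the MHC class II (0.24), Fc receptor (-0.22), classical (0.40) and C-type lectin (0.01) calls, and replicate 3 the classical (0.18) and C-type lectin (0.08) calls. WT PBS replicate 2 was needed for the classical (0.40 without it) and C-type lectin (0.08) calls, and MHC class II and B cell medians were then 0.58 and 0.35. WT PBS replicate 3 was needed for the same calls (0.31 and 0.09), and Fc receptor and B cell medians were then -0.15 and 1.60. The B cell median was 0.33 without WT PBS replicate 1. The C-type lectin call also needed FcgRIIb knockout IVIg replicate 1 (0.02) and 3 (0.01) and WT IVIg replicate 1 (0.02), and its median was 0.00 without Dectin-1 knockout PBS replicate 1 and 0.01 without WT IVIg replicate 3.

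The same lists moved under other settings. Fc receptor signalling genes lost their call with own groups only (-0.22), without the most alike WT pair and the shallow library (-0.13) and with the abundant-gene form of the length correction (-0.23), turned to 0.04 with its first form, and had -0.39 with its revised form. Classical markers lost theirs without the most alike pair (0.29), also without the shallow library (0.39), and with the revised form (0.12), and had 0.86 with the first form. MHC class II genes lost theirs with the revised form (0.07), and had 0.54 and 0.18 in the first and centred forms, 0.48 with own groups only and 0.20 without the most alike pair. B cell markers had 1.58 without the most alike pair, with the shallow library kept or left out. The C-type lectin call was lost with own groups only (0.00), without the most alike pair (0.05), also without the shallow library (0.02), and in the centred (0.01) and abundant-gene (0.07) forms. Its median turned to -0.03 with no low-count filter and -0.04 in the revised form, both without a call, and was 0.21 in the first form, 0.04 with the stricter filter and 0.01 with RLE size factors and without immunoglobulin, haemoglobin and mitochondrial genes.

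In WT mice, IVIg went with more transcript of non-classical monocyte genes. Of 28 markers 27 were higher, with a median log2 fold change of 0.60 (camera adjusted p = 5.01e-23, and adjusted p = 0.00874 with an estimated correlation). Cd300e stood at 122 ± 40.4 CPM with PBS and 268 ± 62.0 with IVIg, and Eno3 at 98.1 ± 11.5 and 231 ± 60.9 (SD, n = 3 each), with all IVIg libraries above all PBS libraries. In edgeR 9 members passed adjusted over the list alone and 0 over all genes. The median was 0.35 without WT IVIg replicate 2, and the list still passed. With the length trend removed as well, camera with an estimated correlation gave adjusted p = 0.511, 0.0276, 0.242 and 0.0338 in the first, centred, abundant-gene and revised forms. Classical monocyte markers had a median of -0.18, with 15 of 25 lower and Chil3, a chitinase-like protein, at -1.25 ± 0.46 (camera adjusted p = 0.0324, and adjusted p = 0.562 with an estimated correlation). Their call was lost without WT PBS replicate 1 (0.03), WT IVIg replicate 1 (-0.07) or WT IVIg replicate 2 (0.00), and the median was -0.44 without WT IVIg replicate 3. Of the Fc receptors, Fcgr4, an activating receptor, gave 0.83 ± 0.38, Fcgr1 -0.43 ± 0.25, Fcgr3 -0.06 ± 0.23 and Fcgr2b -0.07 ± 0.24 (log2 fold change and SE), and none passed in edgeR. The non-classical median was 0.78 without the most alike pair, WT PBS replicate 3 and WT IVIg replicate 1. A label swap or shared batch cannot be decided.

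**Figure D3:**
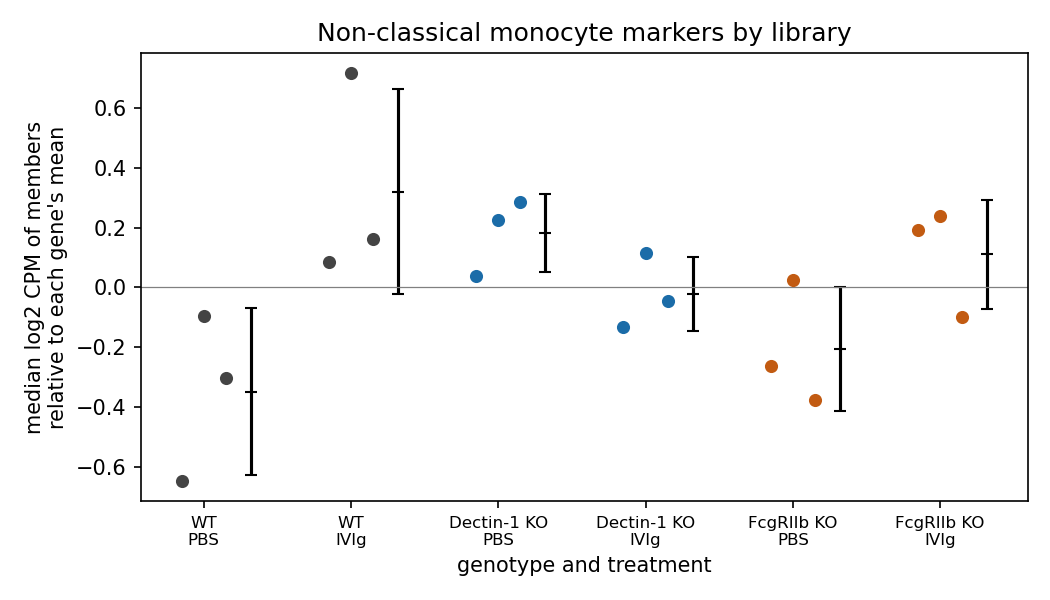
Median log2 CPM of the non-classical monocyte markers, relative to each gene's mean over libraries, in each of the 18 libraries by genotype and treatment, with the mean and SD of each group. The WT IVIg libraries lie between 0.09 and 0.72 and the WT PBS libraries between -0.65 and -0.10, while the ranges of PBS and IVIg overlap in both knockouts.

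The other 8 lists that passed camera in WT with the preset correlation did not with an estimated one. Adjusted p was then 0.532 for the respiratory chain, 0.512 for the interferon, immediate early, cell cycle, MHC class II and plasma cell lists, and 0.215 for erythroid and T cell markers. Type I interferon genes had a median of -0.18 with 30 of 37 lower and Oas3 at -0.55 ± 0.23, and immediate early genes one of -0.25, with Egr1, a transcription factor, at -2.76 ± 0.68. Respiratory chain genes had 59 of 59 members up with a median of 0.33, cell cycle genes a median of 0.33 with Mcm5 at 0.75 ± 0.28, and MHC class II genes 0.30 with H2-Aa at 0.70 ± 0.37. Plasma cell markers had a median of 1.80, with Mzb1 at 1.80 ± 0.68. Erythroid markers had a median of 0.61, with Hbb-bt at 1.70 ± 0.75, and T cell markers -0.46, with Thy1 at -1.35 ± 0.53. Without immunoglobulin, haemoglobin and mitochondrial genes the erythroid (0.35, adjusted p = 0.249) and plasma cell (0.92, adjusted p = 0.0734) calls of camera were lost. Fold changes ran with gene length here too (Spearman rho = -0.42 across 5281 genes, which are not independent replicates).

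Most of these lists depended on 1 library. Without WT IVIg replicate 2 the MHC class II (-0.11), cell cycle (0.14), immediate early (-0.13), plasma cell (0.53) and erythroid (0.14) calls were lost, and respiratory chain and T cell medians were 0.21 and -0.90. Without WT IVIg replicate 1 the T cell call was lost (-0.42), and medians were 0.49 for MHC class II, 0.53 for the respiratory chain and 1.02 for erythroid markers. WT IVIg replicate 3 decided the plasma cell list, which had a median of -0.01 without it, and the respiratory chain and immediate early medians were then 0.19 and -0.38. The MHC class II (0.26), plasma cell (1.51) and erythroid (0.59) lists missed the threshold without WT PBS replicate 1, and the immediate early list (-0.12) without WT PBS replicate 2. The interferon (-0.02) and plasma cell (1.80) calls were lost without WT PBS replicate 3, with T cell and erythroid medians of -0.12 and 1.04. Plasma cell markers (1.80) also missed it without FcgRIIb knockout PBS replicate 1, 2 or 3 or IVIg replicate 1.

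Without the most alike WT pair, with the shallow library kept or left out, camera lost the interferon (-0.13 and -0.10), classical (-0.16 and -0.13) and T cell (-0.30 and -0.26) calls in WT. Medians were then 0.51 and 0.55 for MHC class II and 1.18 and 1.21 for erythroid markers, and 0.50 for the cell cycle without all of these libraries. Own groups only ended the MHC class II (0.27), classical (-0.20) and plasma cell (0.38) calls, no low-count filter the classical (-0.19), immediate early (-0.26) and plasma cell (1.79) calls, and the stricter filter the plasma cell call (1.80). The MHC class II call was lost in the first (0.24) and abundant-gene (0.20) forms of the length correction, and the plasma cell call in the centred (1.65) and revised (1.55) forms. Abundant-gene and revised forms gave 0.17 and 0.18 for the respiratory chain and 0.40 and 0.40 for erythroid markers, and the centred form -0.11 for classical markers.

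By gene, edgeR called 1 of 17040 in WT, the gene model Gm9574, at 4.49 ± 3.32 CPM with PBS and 0.124 ± 0.197 with IVIg (SD, n = 3 each, edgeR adjusted p = 0.0189). The call was lost without WT PBS replicate 1 (edgeR adjusted p = 0.203) or 3 (0.145), and without WT IVIg replicate 1 (0.0559), 2 (0.532) or 3 (0.485). It was also lost without Dectin-1 knockout PBS replicate 1 (edgeR adjusted p = 0.0541), 2 (0.055) or 3 (0.0581) or Dectin-1 knockout IVIg replicate 3 (0.0514). Neither DESeq2 (adjusted p = 0.370) nor limma voom (0.441) called Gm9574, nor did edgeR with the legacy fit (1), own groups only (0.9995) or the most alike WT pair left out (0.147). At an unadjusted p under 0.05 there were 428 genes against 852 by chance, and DESeq2 called 1 and limma voom 0. The side of chance depended on fit and libraries. Such counts were 1837 with limma voom, 214 with the legacy fit and 247 (1455 by chance) with DESeq2, 844 (886) without the most alike WT pair and 1034 (881) also without the shallow library, and 1835 (898) and 255 (899) without WT IVIg replicates 1 and 2.

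In the Dectin-1 knockout, IVIg libraries held more transcript of granulocyte genes, unevenly between mice. Neutrophil markers had a median log2 fold change of 2.91, with 21 of 22 members up (camera adjusted p = 7.36e-18, and adjusted p = 0.118 with an estimated correlation). Retnlg, a neutrophil-secreted resistin-like protein, stood at 18.7, 53.7 and 4.51 CPM in the IVIg libraries and 0.786 ± 0.561 in PBS (SD, n = 3). S100a8, an abundant neutrophil calprotectin subunit chosen after its values were seen, stood at 113, 250 and 14.6 CPM against 9.54 ± 3.68 (SD, n = 3). In the FcgRIIb knockout libraries S100a8 ranged from 6.15 to 28.6 CPM and Retnlg from 0 to 6.68 CPM, so replicate 3 lay within those ranges. The neutrophil median was 1.34 without Dectin-1 knockout IVIg replicate 2, and 13 members passed in edgeR adjusted over the list alone. Eosinophil and basophil markers had a median of 2.44, with Ear1 at 4.35 ± 1.22 and Hdc, the histamine-forming enzyme, at 2.38 ± 0.66, and B cell markers one of 1.03, with Vpreb3 at 2.85 ± 0.74 (adjusted p = 0.298 for both with an estimated correlation). The eosinophil and basophil median was 0.50 with the stricter low-count filter, where camera lost the call (adjusted p = 0.125), and 0.53 with no filter. Non-classical monocyte markers had a median of -0.16, with 23 of 28 lower and Ear2, a ribonuclease, at -0.75 ± 0.37 (camera adjusted p = 0.00518, and adjusted p = 0.499 with an estimated correlation). Fcgr4 gave -0.58 ± 0.38. Over all genes edgeR called 0 of 17040, with 557 at an unadjusted p under 0.05 against 852 by chance, but 1291 with limma voom, above chance, and 325 (694 by chance) with the stricter filter. DESeq2 called 2, Retnlg among them, and limma voom 0, and edgeR called 13 without Dectin-1 knockout IVIg replicate 3.

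With the preset correlation 8 lists passed camera in the Dectin-1 knockout and 0 with an estimated one. T cell markers had a median of 0.64 with Thy1 at 1.38 ± 0.58, and progenitor markers 0.32 with Mpo, a granule peroxidase, at 2.95 ± 0.86 (adjusted p = 0.368 for both with an estimated correlation). The unfolded protein response had a median of 0.20 (adjusted p = 0.557 with an estimated correlation) and immediate early genes 0.09, with Egr1 at 2.52 ± 0.82 (adjusted p = 0.429 with an estimated correlation). Without Dectin-1 knockout IVIg replicate 2 camera lost the eosinophil (1.18), B cell (0.24), T cell (0.57), progenitor (0.44), immediate early (0.08) and unfolded protein (0.19) calls. Unfolded protein and progenitor calls were lost without IVIg replicate 1 (0.22 and 0.64) and PBS replicate 1 (0.18 and 0.32), and the latter also ended the immediate early call (0.04). PBS replicate 3 was needed for the non-classical (-0.11), unfolded protein (0.15), immediate early (0.12) and progenitor (0.37) calls. Medians were 0.15 for immediate early genes, 0.99 for T cell and 0.69 for progenitor markers without PBS replicate 2, and 0.16 for immediate early genes without IVIg replicate 3. Progenitor markers (0.32) also missed the threshold without FcgRIIb knockout PBS replicate 2, with own groups only (0.27), with the stricter filter (0.29), without the most alike WT pair and the shallow library (0.33) and in all 4 forms of the length correction (0.32 to 0.35), and had 0.79 with no filter. Own groups only ended the T cell call (0.52), and the first form of the length correction the non-classical (-0.11) and unfolded protein (0.18) calls. In the abundant-gene and revised forms non-classical markers had -0.09 in both and immediate early genes 0.13 in both.

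In the FcgRIIb knockout, IVIg went with higher NK cell, cell cycle and interferon gamma gene lists by camera with the preset correlation. With an estimated correlation adjusted p was 0.341 for NK cell markers and 0.714 for the cell cycle and interferon gamma lists. NK cell markers had 19 of 20 members up and a median log2 fold change of 0.80, with Klrb1c at 2.61 ± 0.73. Cell cycle genes had a median of 0.52, with Plk1, a mitotic kinase, at 2.53 ± 0.89, and interferon gamma genes 0.34, with Gbp2, a guanylate-binding protein, at 0.92 ± 0.22. Non-classical markers had a median of 0.40 with 22 of 28 up, and Cd300e stood at 130 ± 22.3 CPM with PBS and 199 ± 37.0 with IVIg (SD, n = 3 each). Camera gave the non-classical list adjusted p = 0.0379, and adjusted p = 0.714 with an estimated correlation. That call was lost with RLE size factors (0.37), the stricter low-count filter (0.40), own groups only (0.34), and the first (0.05, camera adjusted p = 0.602), centred (0.35) and abundant-gene (0.31) forms of the length correction. Respiratory chain genes had a median of -0.24, cholesterol synthesis genes -0.32, with Fdps at -0.86 ± 0.33, and erythroid markers 0.69, with Hbb-bs at 1.66 ± 0.55. At an estimated correlation adjusted p was 0.812 for the respiratory chain and 0.714 for the cholesterol and erythroid lists. Adjusted p in camera was 0.000573 for NK cell markers. Fcgr4 gave 0.75 ± 0.41. By gene, edgeR called 0 of 17040, with 543 at an unadjusted p under 0.05 against 852 by chance, while DESeq2 called 31 and limma voom 0. The unadjusted count was above chance with DESeq2 (1175 against 810) and without FcgRIIb knockout PBS replicate 1 (1468 against 908), and below it with own groups only (270 against 725) and without IVIg replicate 1 (822 against 904) or 2 (333 against 904). In edgeR 1 gene was called without FcgRIIb knockout IVIg replicate 3.

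The PBS libraries of the FcgRIIb knockout decided most of these 7 lists. Without FcgRIIb knockout PBS replicate 1 the interferon gamma (0.39), non-classical (0.39), cell cycle (0.62), cholesterol (-0.48), NK cell (0.65) and erythroid (0.88) calls were lost, and the respiratory chain median was -0.52. Without PBS replicate 3 the interferon gamma (0.40), non-classical (0.41), cell cycle (0.57), cholesterol (-0.14) and erythroid (1.40) calls were lost, and the respiratory chain median turned to 0.23. Leaving out IVIg replicate 2 ended the interferon gamma (0.23), non-classical (0.30), cell cycle (0.16), respiratory chain (-0.14), cholesterol (-0.17) and erythroid (0.67) calls. IVIg replicate 1 was needed for the non-classical (0.34) and erythroid (0.95) calls, with medians then of -0.54 for the respiratory chain and -0.48 for cholesterol synthesis. IVIg replicate 3 was needed for the respiratory chain (-0.10), with an erythroid median then of 1.29. Erythroid markers also lost their call without immunoglobulin, haemoglobin and mitochondrial genes (0.36, camera adjusted p = 0.322), with no low-count filter (0.43) and in the centred (0.70) and revised (0.77) forms of the length correction. Interferon gamma genes lost theirs with own groups only (0.34) and in the first (0.18) and abundant-gene (0.30) forms. The first form gave -0.47 for the respiratory chain and -0.49 for cholesterol synthesis, and the revised form -0.13 for the respiratory chain.

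Averaged over the genotypes, cell cycle, neutrophil and non-classical gene lists were higher with IVIg by camera with the preset correlation (adjusted p = 0.258, 0.207 and 0.207 with an estimated correlation). Cell cycle genes had 37 of 40 members up and a median of 0.37 (camera adjusted p = 1.12e-08), with Tpx2, a spindle protein, at 1.19 ± 0.35. Non-classical markers had a median of 0.25, with Cd300e at 0.46 ± 0.16, and neutrophil markers one of 1.37, with Ngp at 1.88 ± 0.73. In WT, the Dectin-1 knockout and the FcgRIIb knockout the medians were 0.60, -0.16 and 0.40 for non-classical and -0.06, 2.91 and 0.41 for neutrophil markers, against 0.33, 0.23 and 0.52 for the cell cycle. The classical list had a median of -0.17, with Chil3 at -0.86 ± 0.26 (adjusted p = 0.433 with an estimated correlation). The other lists with higher medians were erythroid (0.71), plasma cell (0.73), with Mzb1 at 1.46 ± 0.40, NK cell (0.44), MHC class II (0.19) and B cell (0.18), and cholesterol synthesis had -0.12, with Idi1 at -0.47 ± 0.14. By genotype, in the same order, B cell medians were 0.02, 1.03 and -0.07 and cholesterol medians -0.14, 0.01 and -0.32. None of the 10 passed with an estimated correlation, where adjusted p lay between 0.161 and 0.588. Of 17040 genes edgeR called 0, with 393 at an unadjusted p under 0.05 against 852 by chance, while DESeq2 called 2 and limma voom 0. That count was 260 with the stricter filter, 595 without the most alike WT pair and the shallow library, 657 without WT IVIg replicate 1 and 769 without FcgRIIb knockout PBS replicate 1.

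Of these averaged lists the MHC class II call was lost without Dectin-1 knockout IVIg replicate 1 (0.18), WT IVIg replicate 2 (0.06), WT PBS replicate 1 (0.12), FcgRIIb knockout IVIg replicate 1 (0.17) or FcgRIIb knockout PBS replicate 1 (0.23) or 3 (0.21). The cholesterol call was lost without Dectin-1 knockout IVIg replicate 2 (-0.09), FcgRIIb knockout IVIg replicate 2 (-0.08) or PBS replicate 3 (-0.07), or WT PBS replicate 1 (-0.09), and its median was -0.20 without FcgRIIb knockout IVIg replicate 1 and -0.19 without WT PBS replicate 3. B cell markers missed the threshold without Dectin-1 knockout IVIg replicate 2 (0.06) or FcgRIIb knockout PBS replicate 3 (0.13). Their median was 0.31 without Dectin-1 knockout IVIg replicate 3, 0.28 without Dectin-1 knockout PBS replicate 2, 0.45 without FcgRIIb knockout PBS replicate 1, 0.11 without WT PBS replicate 2 and 0.50 without WT PBS replicate 3. Plasma cell markers missed it without FcgRIIb knockout PBS replicate 1 (0.54) or 3 (0.69) or WT IVIg replicate 3 (0.40). Classical markers missed it without FcgRIIb knockout PBS replicate 3 (-0.09), and had -0.11 without WT PBS replicate 1. Leaving out FcgRIIb knockout IVIg replicate 2 gave 0.25 for the cell cycle, 0.46 for plasma cell and 0.37 for erythroid markers. Neutrophil markers had 0.88 without Dectin-1 knockout IVIg replicate 2 and 0.80 without WT IVIg replicate 2, which left NK cell markers at 0.22. The erythroid call was lost without immunoglobulin, haemoglobin and mitochondrial genes (0.27, camera adjusted p = 0.152), and the median was 0.47 with the stricter filter. The first form of the length correction ended the MHC class II (0.00) and non-classical (0.13) calls and gave -0.35 for classical markers, and the centred (0.18) and abundant-gene (0.15) forms also ended the MHC class II call. Without the most alike WT pair, with the shallow library kept or left out, medians were -0.20 and -0.22 for cholesterol synthesis and 0.44 and 0.44 for B cell markers.

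The response of non-classical monocyte genes to IVIg differed between Dectin-1 knockout and WT mice. Of 28 markers 26 had a lower IVIg effect in the knockout, with a median difference of -0.81 on the log2 scale, from medians of 0.60 in WT and -0.16 in the knockout. This passed camera (adjusted p = 9.85e-17, and adjusted p = 0.0316 with an estimated correlation), and the median was -0.52 without WT IVIg replicate 2. With the length trend removed as well, the call with an estimated correlation was lost in each form (camera adjusted p = 0.608, 0.0821, 0.182 and 0.0913 in the first, centred, abundant-gene and revised forms). Cd300e gave a difference of -1.48 ± 0.38, from 1.14 ± 0.27 in WT, and in CPM it stood at 257 ± 58.7 with PBS and 202 ± 49.5 with IVIg in the knockout (SD, n = 3 each). Ear2 gave -1.88 ± 0.53, from -0.75 ± 0.37 in the knockout. Fcgr4 gave a difference of -1.41 ± 0.54, from 0.83 ± 0.38 in WT and -0.58 ± 0.38 in the knockout, and did not pass (edgeR adjusted p = 0.999). The knockout had more of these markers with PBS, so the difference involves both treatments, and it shares the WT libraries with the WT effect. In edgeR 7 members passed adjusted over the list alone and 0 over all genes. By gene, edgeR called 0 of 17040, with 638 at an unadjusted p under 0.05 against 852 by chance, and DESeq2 and limma voom called 0. Unadjusted counts were above chance with limma voom (2666), without the most alike WT pair (1091 against 886), also without the shallow library (1301 against 881) and without WT IVIg replicate 1 (1817 against 898), and were 389 with the legacy fit and 402 (1455 by chance) with DESeq2. Egr1 gave a difference of 5.28 ± 1.06, from -2.76 ± 0.68 in WT and 2.52 ± 0.82 in the knockout, at group means of 0.412 to 3.33 CPM in these genotypes.

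Lists of other blood cells also differed in IVIg effect between these genotypes by camera with the preset correlation. With an estimated correlation adjusted p for these 7 lists lay between 0.131 and 0.852. Neutrophil markers differed by a median of 2.44, with Ngp at 5.70 ± 1.71, eosinophil and basophil markers by 2.21, with Hdc at 3.46 ± 0.89, B cell markers by 1.37 and T cell markers by 1.26, with Thy1 at 2.73 ± 0.79. The unfolded protein response differed by 0.36, immediate early genes by 0.35 and the respiratory chain by -0.34. Without the most alike WT pair camera lost the B cell (0.41, adjusted p = 0.510) and eosinophil and basophil (0.92, adjusted p = 0.0956) calls, and T cell markers differed by 0.71. With the shallow library left out too these medians were 0.37, 0.88 and 0.65, with the same 2 calls lost. The eosinophil and basophil median was 0.10 with the stricter low-count filter, where the call was lost (camera adjusted p = 0.185), and 1.19 with no filter. Abundant-gene and revised forms of the length correction gave -0.17 and -0.17 for the respiratory chain and 0.54 and 0.54 for immediate early genes. Unfolded protein genes lost the call without Dectin-1 knockout IVIg replicate 1 (0.35), WT IVIg replicate 2 (0.20) or WT PBS replicate 2 (0.31). B cell markers lost it without Dectin-1 knockout IVIg replicate 2 (0.11) or PBS replicate 1 (1.15), WT IVIg replicate 1 (1.23) or WT PBS replicate 3 (0.22). Eosinophil and basophil markers lost it without Dectin-1 knockout IVIg replicate 2 (1.01) or PBS replicate 2 (1.21), WT IVIg replicate 1 (1.13) or WT PBS replicate 2 (0.91). That median was 3.68 without WT IVIg replicate 2 and 0.97 to 1.38 without Dectin-1 knockout IVIg replicate 1 or PBS replicate 3, WT PBS replicate 1 or 3, or any of the 6 FcgRIIb knockout libraries. The respiratory chain median was -0.60 without Dectin-1 knockout IVIg replicate 1, -0.21 without replicate 3 of that group and -0.55 without WT IVIg replicate 1. Neutrophil markers had 1.44 without Dectin-1 knockout IVIg replicate 2 and 4.04 without WT IVIg replicate 2, which left immediate early genes at 0.23.

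Between the FcgRIIb knockout and WT, interferon genes had a higher IVIg effect in the knockout and respiratory chain genes a lower one by camera with the preset correlation. Adjusted p with an estimated correlation was 0.684 for both interferon lists and the respiratory chain. Gbp2 gave a difference of 1.13 ± 0.29, from 0.92 ± 0.22 in the knockout, and Oas3 one of 0.85 ± 0.33, from -0.55 ± 0.23 in WT. Medians differed by 0.23 for type I interferon, 0.26 for interferon gamma, 1.22 for T cell and 0.38 for NK cell genes, by -0.26 for non-classical markers and by -0.54 for the respiratory chain, where 59 of 59 members were lower. With an estimated correlation adjusted p for these 6 lists lay between 0.601 and 0.684. The type I interferon call was lost with the first form of the length correction (0.11, camera adjusted p = 0.585) and without the most alike WT pair and the shallow library (0.27, adjusted p = 0.198). Fcgr4 differed by -0.08 ± 0.56. By gene, edgeR called 0 of 17040, with 487 at an unadjusted p under 0.05 against 852 by chance, while DESeq2 called 2 and limma voom 0. That count was above chance with limma voom (1066), without the most alike WT pair and the shallow library (913 against 881), WT IVIg replicate 1 (1187 against 898) or FcgRIIb knockout PBS replicate 1 (1479 against 908). Without FcgRIIb knockout PBS replicate 3 it was 303 and without IVIg replicate 1 835. The comparisons with both knockouts share the WT libraries, so they are not independent.

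Interferon gamma genes lost this call without FcgRIIb knockout IVIg replicate 1 (0.35) or 2 (0.19), PBS replicate 1 (0.39) or 3 (0.32), WT IVIg replicate 1 (0.21) or WT PBS replicate 2 (0.18) or 3 (0.20). Their median was 0.43 without WT IVIg replicate 2 and 0.51 without WT PBS replicate 1. NK cell markers lost it without FcgRIIb knockout IVIg replicate 1 (0.24) or PBS replicate 1 (0.90), WT IVIg replicate 1 (0.57) or WT PBS replicate 2 (0.62), and had 0.80, 1.17 and 0.96 without FcgRIIb knockout IVIg replicate 3, PBS replicate 3 and WT IVIg replicate 2. Non-classical markers lost it without FcgRIIb knockout PBS replicate 2 (-0.21), WT IVIg replicate 2 (-0.07) or WT PBS replicate 1 (-0.17), and had -0.17 without FcgRIIb knockout IVIg replicate 3 and -0.46 without WT IVIg replicate 3. The respiratory chain had -0.86 and -0.88 without replicate 1 of the FcgRIIb knockout IVIg and PBS groups and -0.11 without PBS replicate 3. Type I interferon genes had 0.36 without WT PBS replicate 1 and 0.04 without WT PBS replicate 3.

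Without the most alike WT pair, with the shallow library kept or left out, the interferon gamma (0.14 and 0.04), T cell (0.77 and 0.76) and NK cell (0.32 and 0.27) differences lost their calls. Interferon gamma genes also lost theirs with own groups only (0.27) and in the first (0.27) and abundant-gene (0.36) forms of the length correction. NK cell markers lost theirs with the stricter filter (0.27), and had 0.61 with no filter and 0.69 and 0.68 in the abundant-gene and revised forms. The first form gave -0.58 for non-classical markers and the revised form -0.29 for the respiratory chain.

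Across all genes, the IVIg effects in the 3 genotypes were weakly and negatively related. Spearman's rho across 17040 genes was -0.12 between WT and the Dectin-1 knockout, -0.05 between WT and the FcgRIIb knockout and -0.09 between the knockouts. It turned to 0.01 for the first pair without WT PBS replicate 3 and to 0.07 for the last without FcgRIIb knockout PBS replicate 1. For WT and the FcgRIIb knockout it turned to 0.12 without FcgRIIb knockout PBS replicate 3, 0.04 without FcgRIIb knockout IVIg replicate 3, 0.03 without WT PBS replicate 1 and 0.01 without WT IVIg replicate 3. Without the most alike WT pair it was -0.02 there. Fold changes with IVIg ran with gene length in opposite directions, at rho of -0.42 in WT and 0.27 and 0.24 in the Dectin-1 and FcgRIIb knockouts (5281 genes). Over the 4 forms of the length correction the 3 correlations were -0.11 to -0.10, -0.07 to -0.04 and -0.10 to -0.07. Genes are not independent replicates, and no p is given. Each pair of effects came from separate libraries.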

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

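Chosen after the result was seen were the tests on natural killer markers, the use of the Fisher test around Clec7a, itself fixed beforehand, to weigh explanations, the test on loss of Dectin-1, the revised length correction, the test on classical markers, the splits for the WT non-classical list, the removals of the length trend, with the preset and with an estimated correlation, and the removal of the most alike WT pair.

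Of 224 genes within 10 Mb of Clec7a, 5 were called in the Dectin-1 knockout against WT with PBS, against 1 of 16815 elsewhere. Fewer natural killer cells in the knockout sort are argued against for the 3 called genes that were higher in the knockout (Hebp1, Klra17 and Emp1). For the lower ones, Klri2 and Eps8, they are argued against by the 11 of 20 NK cell markers farther than 10 Mb from Clec7a, which had a median of 0.32 and, summed without the abundant S1pr5 because most are scarce, 9.15 ± 2.40 CPM in WT and 8.98 ± 4.17 in the knockout with PBS (SD, n = 3 each, 98.1% of WT), while Eps8 was 11.9-fold lower. The clustering (two-sided Fisher's exact test, p = 2.23e-09) is what donor strain sequence kept around the target would give, and it may account for these genes, though the strain of the targeted cells is not given in the sources used here. Loss of Dectin-1 cannot be told apart from it, because 0 libraries of the knockout line hold Clec7a at the level of the other lines.

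Respiratory chain genes were higher in the FcgRIIb knockout than in WT with PBS, 58 of 59 members, with a median of 0.86 (0.39 without FcgRIIb knockout PBS replicate 3) and adjusted p = 0.428 with an estimated correlation in camera. The low depth of FcgRIIb knockout PBS replicate 2 is argued against, since the median was 0.942 without that library. These genes are short (median length 1801 bases against 4620 for all), and removal of the length trend gave 0.817 in its first form, 0.623 centred, 0.492 with abundant genes and 0.374 with both (camera adjusted p = 1.17e-24, 3.94e-26, 5.10e-19 and 4.11e-14, and adjusted p = 0.982, 0.303, 0.532 and 0.617 with an estimated correlation). The first value met the bound set in advance against gene length, but that bound was wrong, since this form left a rho of -0.20 with length in this comparison and moved the median of the genes tested for it by 0.24. Gene length bias and a difference between the genotypes, which was not tested, cannot be told apart here, because the list passed in all 4 forms with the preset correlation but in none beyond the spread between libraries that the estimated one counts, and the form that left the least trend (rho of 0.00487) left 43.6% of the median.

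Non-classical monocyte markers were higher with IVIg in WT by a median of 0.60 and differed by -0.81 in the Dectin-1 knockout. These share the WT libraries and were 0.35 and -0.52 without WT IVIg replicate 2. Removal of the length trend left 0.556 and 0.536 in WT and -0.741 and -0.699 for the difference (first and revised form), and removal of the most alike WT pair 0.785 and -0.910, which argues against either as the whole cause of these medians. With an estimated correlation the length correction left camera adjusted p = 0.511 and 0.0338 in WT and 0.608 and 0.0913 for the difference, so the difference no longer passed in either form, nor WT in the first, as medians were smaller and the correlation estimated for the difference rose from 0.159 to 0.601 and 0.208. A larger share of non-classical cells in the sort cannot be told apart from a change within cells, because the fall of classical markers it needs (median -0.183, camera adjusted p = 0.0324) is lost with an estimated correlation (adjusted p = 0.562). For the difference, 2 of 100 random genotype assignments gave a median as far from 0 (real -0.81, highest other 0.814 in size). These also shuffle the genotype difference with PBS and ignore the choice among 29 lists, so chance is not excluded. That Dectin-1 shapes this response remains a hypothesis found and tested on the same data.

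The counts of called genes in edgeR were set against other splits of the libraries. For comparisons of 3 against 3 libraries 10 splits cannot give a share under 0.05. In WT the real split called 1 gene and the highest other 556, with 4 of 10 splits calling as many, and the WT non-classical median had 1 of 10 (real 0.60, highest other 0.514). For the Dectin-1 knockout against WT the real count was 7 (highest other 0, 1 of 10). A real count of 0 is met by each split, so these counts test nothing for IVIg in the Dectin-1 knockout (10 of 10, highest other 1), IVIg in the FcgRIIb knockout (10 of 10, highest other 19) and the FcgRIIb knockout against WT (10 of 10, highest other 10). The same holds for the averaged effect and the differences in effect of the Dectin-1 and FcgRIIb knockouts (100 of 100 assignments each, highest others 2139, 662 and 316). The WT split with 556 genes set WT PBS replicate 1 and WT IVIg replicates 2 and 3 against WT PBS replicates 2 and 3 and WT IVIg replicate 1, a structure of the samples that does not follow treatment and for which the labels give no batch. The assignment that called 2139 genes divided the WT libraries in the same way, and those that called 662, 316 and 10 also set WT PBS replicate 1 apart from replicates 2 and 3. Expression ran with gene length at Spearman rho of 0.25, -0.30 and -0.35 in the first 3 libraries and 0.36, 0.54 and 0.58 in the others, across 5281 genes that are not independent replicates.

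The other lists whose IVIg effect differed between the Dectin-1 knockout and WT by camera with the preset correlation follow, with the WT and knockout medians. Neutrophil markers differed by 2.44 (-0.06 and 2.91, adjusted p = 0.131 with an estimated correlation), and by 1.44 without Dectin-1 knockout IVIg replicate 2 and 4.04 without WT IVIg replicate 2. T cell markers differed by 1.26 (-0.46 and 0.64, adjusted p = 0.131 with an estimated correlation), and by 0.71 without the most alike WT pair. B cell markers differed by 1.37 (0.02 and 1.03, adjusted p = 0.668 with an estimated correlation), a call lost without Dectin-1 knockout IVIg replicate 2 (0.11) or PBS replicate 1 (1.15), WT IVIg replicate 1 (1.23) or WT PBS replicate 3 (0.22), or without the most alike WT pair (0.41). Eosinophil and basophil markers differed by 2.21 (-0.62 and 2.44, adjusted p = 0.247 with an estimated correlation), a call lost without Dectin-1 knockout IVIg replicate 2 (1.01) or PBS replicate 2 (1.21), WT IVIg replicate 1 (1.13) or WT PBS replicate 2 (0.91), without the most alike WT pair (0.92) or with the stricter filter (0.10). That median was 3.68 without WT IVIg replicate 2 and 0.97 to 1.38 without most other single libraries. Immediate early genes differed by 0.35 (-0.25 and 0.09, adjusted p = 0.247 with an estimated correlation), and by 0.23 without WT IVIg replicate 2. The unfolded protein response differed by 0.36 (-0.16 and 0.20, adjusted p = 0.438 with an estimated correlation), a call lost without Dectin-1 knockout IVIg replicate 1 (0.35), WT IVIg replicate 2 (0.20) or WT PBS replicate 2 (0.31). The respiratory chain differed by -0.34 (0.33 and -0.02, adjusted p = 0.852 with an estimated correlation), and by -0.60 without Dectin-1 knockout IVIg replicate 1, -0.21 without replicate 3 of that group and -0.55 without WT IVIg replicate 1.

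Between the FcgRIIb knockout and WT 6 lists differed in IVIg effect by the same test, again with the WT and knockout medians. Type I interferon genes differed by 0.23 (-0.18 and 0.13, adjusted p = 0.684 with an estimated correlation), by 0.36 without WT PBS replicate 1 and by 0.04 without WT PBS replicate 3, a call lost with the first form of the length correction (0.11). Interferon gamma genes differed by 0.26 (0.02 and 0.34, adjusted p = 0.684 with an estimated correlation), a call lost without FcgRIIb knockout IVIg replicate 1 (0.35) or 2 (0.19), PBS replicate 1 (0.39) or 3 (0.32), WT IVIg replicate 1 (0.21) or WT PBS replicate 2 (0.18) or 3 (0.20), or without the most alike WT pair (0.14). Non-classical markers differed by -0.26 (0.60 and 0.40, adjusted p = 0.604 with an estimated correlation), a call lost without FcgRIIb knockout PBS replicate 2 (-0.21), WT IVIg replicate 2 (-0.07) or WT PBS replicate 1 (-0.17). The respiratory chain differed by -0.54 (0.33 and -0.24, adjusted p = 0.684 with an estimated correlation), and by -0.86 and -0.88 without replicate 1 of the FcgRIIb knockout IVIg and PBS groups and -0.11 without PBS replicate 3. T cell markers differed by 1.22 (-0.46 and 0.86, adjusted p = 0.601 with an estimated correlation), a call lost without the most alike WT pair (0.77). NK cell markers differed by 0.38 (0.02 and 0.80, adjusted p = 0.601 with an estimated correlation), a call lost without FcgRIIb knockout IVIg replicate 1 (0.24) or PBS replicate 1 (0.90), WT IVIg replicate 1 (0.57) or WT PBS replicate 2 (0.62), without the most alike WT pair (0.32) or with the stricter filter (0.27).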

How the results depend on the processing

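Tests with limma voom, without the most alike WT pair or without the length trend were chosen after the data were seen. No paired analysis was possible because the titles carry no replicate numbers and only 1 of their codes, whose meaning is not given, is shared by libraries of different groups (WT IVIg replicate 3 and FcgRIIb knockout PBS replicate 3). The count for WT IVIg was 0 with a stricter filter, the legacy fit, own groups only, the most alike WT pair left out with or without the shallow library, and limma voom. With no low-count filter edgeR called 1 gene for IVIg in the Dectin-1 knockout and 10 for the FcgRIIb knockout against WT. DESeq2 called 2 genes for IVIg in the Dectin-1 knockout, 31 in the FcgRIIb knockout (8 of them with a mean count under 10 in every group), 2 for the averaged effect, 2 for the FcgRIIb knockout difference, 12 for the Dectin-1 knockout against WT and 209 for the FcgRIIb knockout against WT (22 with such low counts). For the Dectin-1 knockout against WT there were 16 calls without the most alike WT pair, 12 also without the shallow library and 12 with limma voom. The correlation of IVIg effects between WT and the Dectin-1 knockout was -0.20 with the stricter filter. With single libraries left out the counts ranged from 0 to 1 for WT IVIg, 0 to 13 and 0 to 1 for IVIg in the Dectin-1 and FcgRIIb knockouts, 0 to 0 for the averaged effect and both differences, 5 to 10 for the Dectin-1 knockout and 0 to 40 for the FcgRIIb knockout against WT. Over the same fits the Clec7a difference was -9.08 to -8.33, that of Fcgr2b -0.58 to -0.39, calls near Clec7a 4 to 5 and near Fcgr2b 0 to 1. Correlations of IVIg effects were -0.23 to 0.00790 for WT and the Dectin-1 knockout, -0.15 to 0.12 for WT and the FcgRIIb knockout and -0.19 to 0.0699 for the knockouts, and non-classical medians 0.35 to 0.76 in WT and -0.92 to -0.52 for the Dectin-1 difference. Medians that turned were MHC class II in WT IVIg (-0.11 without WT IVIg replicate 2, highest 0.49 without WT IVIg replicate 1), classical markers in WT IVIg (0.0257 without WT PBS replicate 1, 0.00203 without WT IVIg replicate 2, lowest -0.44 without WT IVIg replicate 3), plasma cell markers in WT IVIg (-0.00745 without WT IVIg replicate 3, highest 2.21 without WT IVIg replicate 1) and the respiratory chain in FcgRIIb knockout IVIg (0.23 without PBS replicate 3, lowest -0.54 without IVIg replicate 1). In the FcgRIIb knockout against WT they were Fc receptor signalling (0.0436 with the first length form), C-type lectins (-0.0309 with no low-count filter, -0.0352 with the revised length form) and B cell markers (-0.12 without FcgRIIb knockout PBS replicate 1, highest 1.60 without WT PBS replicate 3). Of the 68 list calls 67 were kept with RLE size factors, 61 with no filter, 62 with the stricter one, 62 without immunoglobulin, haemoglobin and mitochondrial genes, 57 with own groups only, 57 without the most alike pair, 54 to 61 over the 4 length forms, 4 with an estimated correlation and 0 to 5 with both. With both, the non-classical call in WT was lost in the first (0.556) and abundant-gene (0.535) forms, and that for the Dectin-1 difference in all 4 (-0.741, -0.749, -0.701 and -0.699). Removing libraries or genes leaves fewer samples or members to test, and for the other changes the cause was not tested. Depth limits most the FcgRIIb knockout with PBS, where 1 of 3 libraries held 719494 counts.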

Other observations

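The lists of cytokines, metabolism and rarer cells described here, with S100a9 and the length trend per library, were looked at as values, and S100a9 and the length trend were chosen after the data were seen. Glycolysis genes passed camera in none of the 8 comparisons, with the smallest adjusted p (0.0628) for the averaged IVIg effect, where 18 of 25 were higher with a median of 0.04. Dendritic cell markers came closest in the FcgRIIb knockout against WT, with 14 of 22 higher and a median of 0.22 (camera adjusted p = 0.0836). Inflammatory cytokine and NF-kB target genes had 20 of 26 members lower and a median of -0.25 in the Dectin-1 knockout against WT (camera adjusted p = 0.111). Platelet and megakaryocyte markers had 8 of 10 members higher and a median of 0.52 with IVIg in WT (camera adjusted p = 0.113). Genes of alternative activation had 17 of 26 lower and a median of -0.20 with IVIg in WT (camera adjusted p = 0.134), and complement and efferocytosis genes 16 of 29 higher and a median of 0.12 in the Dectin-1 knockout against WT (camera adjusted p = 0.199). Cd36, a scavenger receptor of the complement and non-classical lists, gave 1.36 ± 0.43 in that comparison and 1.25 ± 0.43 with IVIg in WT (log2 fold change and SE) and did not pass in edgeR (adjusted p = 0.909 and 1). Both values share the WT PBS libraries.

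S100a9, the partner of S100a8 in neutrophil calprotectin, stood at 171, 411 and 26.5 CPM in the Dectin-1 knockout IVIg libraries, 0.819 to 21.5 CPM in WT and 3.79 to 15.2 CPM in the Dectin-1 knockout with PBS. In the FcgRIIb knockout it stood at 34.0, 0 and 9.96 CPM with PBS and 31.8, 40.1 and 5.83 CPM with IVIg, so the lowest of the Dectin-1 knockout IVIg libraries lay within that range. Ngp, a neutrophil granule protein, stood at 110, 288 and 4.80 CPM in those Dectin-1 knockout IVIg libraries, 0.328 to 7.09 CPM in WT and 0 to 27.5 CPM in the FcgRIIb knockout. The trend of expression on gene length lay between a Spearman rho of -0.65 in FcgRIIb knockout PBS replicate 3 and FcgRIIb knockout IVIg replicate 1 and 0.58 in WT IVIg replicate 1, across 5281 genes that are not independent replicates.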
